A study of Homo sapiens with 12 samples.

How the data were processed

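Total RNA from T98G cells, an established glioblastoma line, was taken after 72 h without serum and after 10 and 18 h in 10% FBS. The parental line and clone D11 formed the WT group, and clones G6 and B5 the KO group, so each of 6 groups held n = 2 lines. The parental line was not cloned, while D11, G6 and B5 were. Libraries were made per the labels from 500 ng of RNA purified on RNeasy columns, with a stranded total RNA kit. The sample numbers in the column names followed the cell line, so a batch that followed these numbers could not be separated from the line.

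The values were log2 CPM values deposited by the authors, in 2 tables with identical content, of which 1 was used. FastQC, Trimmomatic, TopHat, HTSeq and edgeR with genome build hg38 are credited per the submitters' processing notes, and their versions, their order and the annotation were not given in the sources used here. The table held 13527 genes, 22 of them with symbols turned into dates, which were kept in the tests and not named. A gene with no read had −3.59 log2 CPM (0.0829 CPM) in every library. A prior count averaging 2 reads (1.69 to 2.32 per library) explained this floor, and with it 100% of the values came within 0.1 of whole reads. The recovered reads in the table came to 21.7 to 27.2 M reads per library and the effective library sizes to 20.4 to 28.0 M. At these depths 3 reads equal 0.107 to 0.147 CPM. Gene locations were looked up in GENCODE v29 on GRCh38.

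Tests were run in R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. One limma model with a mean for each of the 6 groups was fitted to all 12 libraries, with the variance trend in the empirical Bayes step. Genes with a mean of at least 0 log2 CPM over the 12 libraries were kept (12464), and two-sided p-values were adjusted by Benjamini-Hochberg over these genes for each contrast, at 0.05. The contrasts were KO against WT at each time, 10 h and 18 h against 0 h in each genotype, and the difference of these serum responses between KO and WT. A further model compared the means of the 3 times, with 1 value per line. These tests, the gene lists, the rule for naming genes and the alternatives, except 3 named below, were chosen before the data were examined.

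The same line was sampled at each time, so the line is a block by design. It was checked by correlating the difference of 2 lines of a genotype across genes between times, which gave 0.596 to 0.653 for D11 minus parental and 0.673 to 0.818 for B5 minus G6. The line entered as a random effect for KO against WT (consensus correlation 0.522) and as a fixed effect for the serum contrasts. The line numbers do not pair WT with KO lines.

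Gene lists were drawn up from general knowledge, 23 in number, and 22 had genes to test. They held G1/S genes, G2/M genes, MuvB, pocket protein and E2F components, Sin3/HDAC complex and partners, APC/C subunits and regulators, CDK inhibitors and quiescence genes, serum immediate-early and delayed-early genes, cholesterol synthesis and uptake, fatty acid synthesis, ribosome biogenesis, cytosolic ribosomal proteins and replication-dependent histones. The others were p53 targets, extracellular matrix, neuronal genes, astrocyte and glial progenitor genes, hypoxia and glycolysis, interferon response, inflammatory cytokines and NF-kB targets, amino acid and ER stress response, lysosome and autophagy, mitochondrially encoded genes and markers of other cell types. None of the 13 mitochondrially encoded genes was in the table. The lists were not exclusive: 3 of the 22 APC/C genes and 3 of the 18 MuvB genes tested were also in another list. Each list was tested by camera with a preset correlation of 0.01, adjusted over 198 tests (22 lists in 9 contrasts), and again with a correlation estimated from the data. Of the 198 tests 65 passed with the preset value, 0 with the estimated one (smallest adjusted p = 0.699) and 34 by fry. Estimating a correlation rests on few residual degrees of freedom with 2 lines per group.

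Named genes were SIN3B, and for KO against WT and for serum in WT up to 8 genes with the largest positive and 8 with the most negative log2 fold change among genes past the threshold. For serum in KO and for the difference in serum response the number was 5. These genes needed a mean of at least 2 log2 CPM, no overlap between the libraries of the compared groups, and a gene symbol. For each list past camera up to 4 members with the smallest p in its direction were named, for other lists up to 2, and where no gene passed in a direction 3 genes were given as values. KCNK1, ITGA7, EFEMP1, FBN2, PCNA and SAT1 fell outside this rule and were chosen after their values were seen. One list member that the rule names is not reported here.

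The tests were tested on simulated data with 12464 genes, of which 100 changed by 1 log2 unit and 100 by 2. At these sizes 39% and 76% were recovered for KO against WT at 0 h, 30% and 83% at 10 h, 26% and 74% at 18 h, and 4% and 61% for the mean of 3 times. For serum in WT the shares were 19% and 84% at 10 h and 23% and 80% at 18 h, and in KO 17% and 78% at 10 h and 17% and 84% at 18 h. For the difference in serum response they were 2% and 41% at 10 h and 0% and 53% at 18 h. False calls were 12 of 127 for KO against WT at 0 h, 10 of 123 at 10 h, 12 of 112 at 18 h and 5 of 70 for the mean of 3 times, above the 5% aimed at, and at most 1 for each other contrast.

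Alternatives were no expression filter, a mean of at least 2 log2 CPM, median-centred values, quantile normalization, a pseudocount of 1 CPM, no variance trend, a fit of only the groups compared, the line as a block, a log2 fold change of at least 1, leaving out each line, and the estimated correlation. Added after seeing the data were voom on the recovered reads, leaving out the B5 0 h library, and the other scalings of the list medians. Where leaving out a line left 1 library in a group, that library was assumed to vary like the other groups. For lists with the line as a block or a line left out, cameraPR was run, a form of camera that works on the genes' test statistics. Its unadjusted p was compared with the largest camera p that passed. A call lost there can therefore reflect the change of test. Overlaps and correlations between contrasts with shared controls were set beside 100 simulated draws of unchanged groups that share the same libraries. Reads were not analysed here, so exon use at the edited SIN3B locus was not examined.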

Results

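T98G glioblastoma cells were held without serum for 72 h and then released into 10% FBS, and total RNA was sequenced at 0, 10 and 18 h. The wild type (WT) group held the parental line and the CRISPR clone D11, and the knockout (KO) group held the SIN3B knockout clones G6 and B5. This gave 12 libraries in 6 groups, with n = 2 lines per group and the same lines sampled at each time. Reads in the gene table for parental, D11, G6 and B5 came to 25.2, 23.1, 22 and 24.7 M reads at 0 h, 21.7, 24.6, 27.2 and 22.5 M at 10 h, and 26.6, 23.6, 24.2 and 23.5 M at 18 h. Of 13527 genes in the table, 12464 were tested. A replicate was a cell line, so p-values of the main limma fit measure the spread between lines. That spread was pooled over the 6 groups, which were treated as independent although the same lines recur in them. With a line left out, it came from the lines of the other genotype alone. Counts of genes from such fits do not show which line carries a difference. Camera p-values with the preset correlation rest on the spread between genes. For serum contrasts with the line as a block, p-values measure the spread of the lines' changes over time. Values below are log2 fold changes with their standard errors (SE), and adjusted p is from limma unless another test is named. The largest rises and falls are ranked among genes past the threshold with a mean of at least 2 log2 CPM, no overlap between the libraries of the compared groups, and a gene symbol.

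SIN3B, the gene targeted in the KO clones, was still read in every KO library. Its log2 CPM in parental, D11, G6 and B5 was 6.15, 6.36, 5.50 and 5.35 at 0 h, 5.83, 5.89, 4.76 and 5.09 at 10 h, and 5.12, 5.59, 4.38 and 4.53 at 18 h. The KO minus WT difference was −0.83 at 0 h (SE 0.20, adjusted p = 0.0887), −0.93 at 10 h (SE 0.20, adjusted p = 0.427) and −0.90 at 18 h (SE 0.20, adjusted p = 0.493). None of these passed 0.05, although each KO library was below each WT library of its time. Against 0 h, SIN3B was −0.40 at 10 h (adjusted p = 0.145) and fell by 0.90 at 18 h (adjusted p = 0.00758) in WT. In KO it was −0.50 at 10 h (adjusted p = 0.102, and 0.0292 with the line as a block) and fell by 0.97 at 18 h (adjusted p = 0.0121). The serum response of SIN3B differed between KO and WT by −0.10 at 10 h (SE 0.28, adjusted p = 1) and −0.07 at 18 h (SE 0.28, adjusted p = 0.993). SIN3A, the paralogue, lay between 6.42 and 6.76 in the 0 h libraries. A knockout allele need not lower its mRNA, and protein was not measured.

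**Figure D1:**
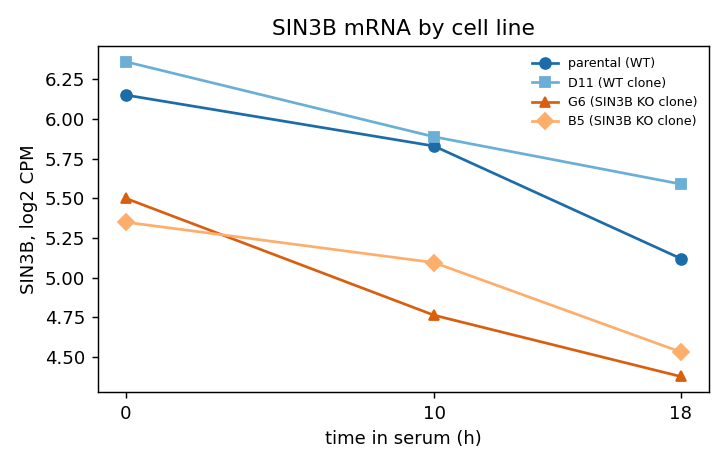
SIN3B level in log2 CPM against time in serum in h, with 1 point per library and lines joining the libraries of each cell line. Both KO clones lie below both WT lines at every time, by 0.83 at 0 h, 0.93 at 10 h and 0.90 at 18 h between group means.

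In serum-starved cells, IL7R, the interleukin 7 receptor chain, was higher in KO by 4.05 (SE 0.69, adjusted p = 0.0492), from 2.05 ± 0.94 to 6.10 ± 0.05 log2 CPM (mean ± SD, n = 2 lines). NT5E, the ecto-5'-nucleotidase CD73, was higher by 4.01 (SE 0.56, adjusted p = 0.0330), and the proteoglycan gene VCAN by 2.19 (SE 0.36, adjusted p = 0.0471). Within these limits of level and overlap, the other genes with the largest rises were the cohesin acetyltransferase gene ESCO2 (2.88, SE 0.51, adjusted p = 0.0497), TTLL7 (2.56, SE 0.43, adjusted p = 0.0481), the glutamate transporter gene SLC1A3 (2.14, SE 0.38, adjusted p = 0.0497), IQGAP2 (2.11, SE 0.24, adjusted p = 0.0182) and DDIAS (1.88, SE 0.24, adjusted p = 0.0275). Lower in KO were the diacylglycerol kinase gene DGKD (−2.35, SE 0.40, adjusted p = 0.0471), FAM101B (−2.22, SE 0.40, adjusted p = 0.0497) and the teneurin gene TENM3 (−2.16, SE 0.33, adjusted p = 0.0398). The MTRNR2L genes, near-identical nuclear copies of mitochondrial rRNA sequence, filled the other places: MTRNR2L9 (−2.04, SE 0.26, adjusted p = 0.0275), MTRNR2L1 (−2.02, SE 0.26, adjusted p = 0.0275), MTRNR2L10 (−1.98, SE 0.32, adjusted p = 0.0471), MTRNR2L8 (−1.87, SE 0.27, adjusted p = 0.0363) and MTRNR2L2 (−1.85, SE 0.28, adjusted p = 0.0398). Their shared sequence makes the value of each copy uncertain. In all, 97 genes passed adjusted p < 0.05 at 0 h, 42 higher and 55 lower in KO, where simulated data with known changes gave 12 false calls of 127. With the line as a random block 28 genes passed, 10 higher and 18 lower. NT5E (adjusted p = 0.0153), VCAN (0.0415), IQGAP2 (0.0321), DDIAS (0.0335), DGKD (0.0321), FAM101B (0.0415), MTRNR2L9 (0.0452) and MTRNR2L1 (0.0452) stayed past it. IL7R, ESCO2, TTLL7, SLC1A3, TENM3, MTRNR2L10, MTRNR2L8 and MTRNR2L2 did not pass with the block. Without parental or without D11 no gene passed, without G6 1353 did and without B5 414 did. Without the B5 0 h library alone 10 genes passed, and when only the 0 h libraries were fitted none did.

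**Figure D2:**
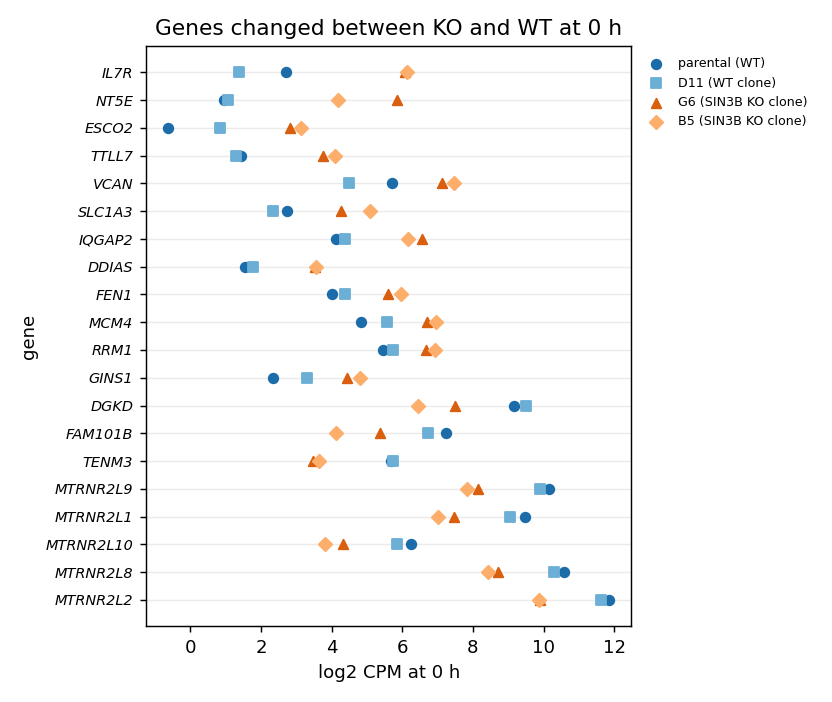
Level at 0 h in log2 CPM of 20 genes that passed the threshold between KO and WT, with 1 point per cell line. The WT and KO points of each gene do not overlap, from IL7R (4.05 higher in KO) to DGKD (2.35 lower in KO).

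Among cell cycle genes at 0 h, the G1/S genes, which encode the replication machinery and its regulators, were higher in KO with a list median of 1.21. MCM4, a subunit of the replicative helicase, rose by 1.63 (SE 0.23, adjusted p = 0.0330), the flap endonuclease gene FEN1 by 1.60 (SE 0.22, adjusted p = 0.0330), the ribonucleotide reductase gene RRM1 by 1.21 (SE 0.21, adjusted p = 0.0492) and GINS1 by 1.78 (SE 0.33, adjusted p = 0.0497). With the line as a block MCM4 passed (adjusted p = 0.0452) and FEN1, RRM1 and GINS1 did not. Of 65 G1/S genes 4 rose and 0 fell over all genes, and 45 rose and 0 fell when adjusted over the list alone. The list test gave adjusted p = 1.14e-22 by camera, and adjusted p = 0.699 with an estimated correlation. The median difference in G1/S genes was 1.60 for G6 minus parental and 1.61 for B5 minus parental, 0.70 for G6 minus D11 and 0.76 for B5 minus D11, beside 0.78 for D11 minus parental. The G2/M genes, which act in mitosis, had a median of 0.98 at 0 h. By line it was 1.39 for G6 minus parental, 1.08 for B5 minus parental, 0.82 for G6 minus D11 and 0.55 for B5 minus D11, beside 0.58 for D11 minus parental, where 79 of 82 genes were above 0. CCNB1 was 1.06 (adjusted p = 0.0503), AURKA 1.05 (adjusted p = 0.0538), PTTG1 1.09 (adjusted p = 0.0728) and CENPI 1.81 (adjusted p = 0.0811), and none passed. For 82 G2/M genes, 0 passed over all genes and 39 rose adjusted over the list alone, with adjusted p = 1.91e-20 by camera and adjusted p = 0.699 with an estimated correlation. In the list of MuvB, pocket protein and E2F components, MYBL1 rose by 1.56 (SE 0.24, adjusted p = 0.0398) and RBL1, encoding p107, by 1.52 (SE 0.27, adjusted p = 0.0497), neither of which passed with the line as a block, while LIN9 was 1.26 (adjusted p = 0.0869) and FOXM1 0.98 (adjusted p = 0.178). That list had a median of 0.29, 2 of 18 genes up over all genes, 3 adjusted over the list alone, camera adjusted p = 0.00384, and adjusted p = 0.699 with an estimated correlation. Without B5 the MuvB list no longer passed (median 0.19).

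Among metabolic and matrix groups at 0 h, cholesterol synthesis and uptake genes had a KO minus WT median of 0.39, but B5 was not above parental. By line the cholesterol median was 0.41 for G6 minus parental and −0.03 for B5 minus parental. It was 0.88 for G6 minus D11 and 0.42 for B5 minus D11, beside −0.46 for D11 minus parental. For these genes 0 of 25 passed over all genes and 1 rose adjusted over the list alone, with camera adjusted p = 0.00439 and adjusted p = 0.712 with an estimated correlation. Amino acid and ER stress response genes had a median of −0.59, with TRIB3 at −1.28 (adjusted p = 0.125) and the chaperone gene HSP90B1 at −0.75 (adjusted p = 0.119). In that list 0 of 28 passed over all genes and 0 adjusted over the list alone, with camera adjusted p = 1.21e-06 and adjusted p = 0.699 with an estimated correlation. The amino acid and ER stress difference came from 1 clone, as the centred list medians of parental, D11, G6 and B5 were 0.94, 1.12, 0.95 and −0.23, and without B5 the median was −0.10 and the call was lost. Extracellular matrix genes had a median of −0.51, with COL12A1 at −2.76 (adjusted p = 0.0963) and COL4A2 at −0.69 (adjusted p = 0.0887) beside the rise of VCAN. Of 33 matrix genes 1 rose over all genes, 1 rose and 3 fell adjusted over the list alone, camera adjusted p was 0.0438, and it was adjusted p = 0.772 with an estimated correlation. Ribosomal protein genes had a median of −0.24, with RPLP0 at −0.45. Of these 0 of 50 passed over all genes and 0 adjusted over the list alone, with camera adjusted p = 0.00313 and adjusted p = 0.916 with an estimated correlation. Calls were also lost without D11 (cholesterol 0.15), without G6 (cholesterol 0.14), without parental (matrix −0.27, ribosomal proteins −0.03) and without B5 (matrix −0.30), and the ribosomal protein median was 0.06 without B5.

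**Figure D3:**
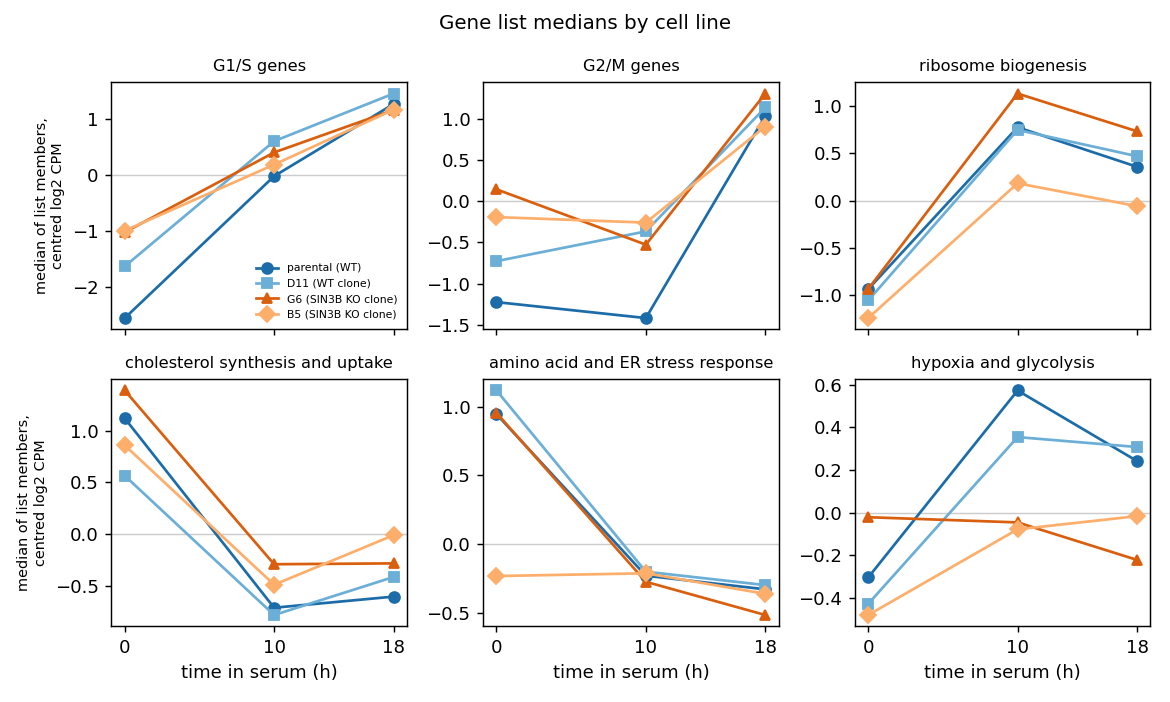
Median of list members in centred log2 CPM against time in serum in h for 6 gene lists, with 1 point per library and lines joining each cell line. At 0 h the G1/S genes lie at −2.56 in parental, −1.64 in D11, −1.03 in G6 and −1.0 in B5, and at 18 h all 4 lines lie between 1.16 and 1.46.

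At 10 h in serum no single gene passed between KO and WT. The cadherin gene CDH6 was −1.24 (SE 0.16, adjusted p = 0.103), TENM3 −2.50 (SE 0.33, adjusted p = 0.105) and the mitophagy receptor gene BNIP3 −1.26 (SE 0.17, adjusted p = 0.106). On the higher side RAB29 was 0.99 (adjusted p = 0.244), the complement factor B gene CFB 1.5 (adjusted p = 0.278) and the polycomb gene CBX7 1.15 (adjusted p = 0.303). By limma 0 genes passed adjusted p < 0.05, 634 had an unadjusted p below 0.05 where 623 are expected by chance, and voom on recovered reads also gave 0. With the line as a block the integrin gene ITGA7 passed (4.64, adjusted p = 0.0470), which without the block had adjusted p = 0.0525. Its mean over the 12 libraries was low, at 0.14 log2 CPM. No gene passed without parental or D11, 706 passed without G6 and 122 without B5.

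Hypoxia and glycolysis genes were lower in KO at 10 h with a median of −0.37, including the prolyl hydroxylase gene EGLN3 at −1.34, the glucose transporter gene SLC2A1 at −1.09, BNIP3 at −1.26 and the demethylase gene KDM3A at −0.77. Of 27 hypoxia genes 0 passed over all genes and 4 fell adjusted over the list alone, with camera adjusted p = 1.39e-08 and adjusted p = 0.699 with an estimated correlation. G2/M genes had a median of 0.50, with PTTG1 at 0.97 and AURKA at 0.68. For 82 G2/M genes 0 passed over all genes and 0 adjusted over the list alone, with camera adjusted p = 8.12e-17 and adjusted p = 0.699 with an estimated correlation. Cholesterol genes had a median of 0.27 (camera adjusted p = 0.00821, and adjusted p = 0.738 with an estimated correlation), and ribosomal protein genes −0.29 (camera adjusted p = 1.62e-08, and adjusted p = 0.763 with an estimated correlation). Only 4 of the 53 replication-dependent histone genes listed were tested, of 7 in the table. Their median was 0.70 (camera adjusted p = 0.0369, and adjusted p = 0.712 with an estimated correlation). Against 0 h, the median of these 4 genes at 10 h was −1.32 in WT and −1.28 in KO. In these 3 lists 0 genes passed over all genes, with HIST2H2BE at 0.81, HIST1H2AC at 0.60 and HIST1H1C at 0.56. The G1/S median was 0.03 (camera adjusted p = 0.543). Calls were lost without parental (G2/M 0.00), without G6 (cholesterol 0.12), without D11 (histones 0.70), without B5 (ribosomal proteins −0.13) and with the block (histones), and the histone median was −0.11 without B5.

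At 18 h in serum CDH6 was still lower in KO by 1.44 (SE 0.16, adjusted p = 0.0452), from 9.97 ± 0.10 to 8.53 ± 0.20 log2 CPM (mean ± SD, n = 2 lines), and it had also fallen at 0 h (−1.77, adjusted p = 0.00803). KCNK1, a potassium channel gene chosen for mention after its value was seen, was −3.37 (SE 0.31, adjusted p = 0.0243), against −3.85 at 0 h (adjusted p = 0.00775) and −2.83 at 10 h (adjusted p = 0.0525). Its mean over the 12 libraries was 1.17 log2 CPM, below the level of 2 asked of the ranked genes. On the higher side none passed, with QPRT at 1.98 (adjusted p = 0.475), CFB at 1.27 and ALAS1 at 0.76. These 2 genes were the only ones past adjusted p < 0.05, with 0 higher and 2 lower, where simulated data gave 12 false calls of 112. With the line as a block 5 genes passed: KCNK1 −3.37, EFEMP1 −3.44, CDH6 −1.44 and ITGA7 3.98 (each adjusted p = 0.0466), and FBN2 −2.24 (adjusted p = 0.0492). Without parental or D11 no gene passed, while 307 did without G6 and 61 without B5, and voom gave 1. Grouping D11 with B5 against parental with G6 gave 4 genes at 18 h and 3 at 10 h. CDH6 missed the threshold with voom (adjusted p = 0.0601), with a mean of at least 2 log2 CPM, with median-centred or quantile values, with no variance trend and with only the groups compared.

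Cholesterol genes were higher in KO at 18 h with a median of 0.43 (camera adjusted p = 2.75e-06, and adjusted p = 0.699 with an estimated correlation), and hypoxia genes were lower with a median of −0.31 (camera adjusted p = 0.000932, and adjusted p = 0.699 with an estimated correlation). In the hypoxia list EGLN3 was −1.38 (adjusted p = 0.32) and BNIP3 −1.0 (adjusted p = 0.32), and 2 genes fell adjusted over the list alone. The histone list had a median of 0.91 (camera adjusted p = 0.00313, and adjusted p = 0.699 with an estimated correlation). By line the histone median was 1.73 for G6 minus parental, 1.13 for B5 minus parental, 0.73 for G6 minus D11 and 0.49 for B5 minus D11. It was 0.91 for D11 minus parental as well. Against 0 h, the histone median at 18 h was −1.21 in WT and −1.06 in KO. Lysosome and autophagy genes had a median of 0.13 (camera adjusted p = 0.00701, and adjusted p = 0.699 with an estimated correlation). The serum immediate-early and delayed-early genes had 0.20 (camera adjusted p = 0.0284, and adjusted p = 0.699 with an estimated correlation), with DUSP4 at 0.95. Ribosomal protein genes had −0.14 (camera adjusted p = 0.0283, and adjusted p = 0.93 with an estimated correlation). Over all genes 0 members of these 6 lists passed. The G1/S median was −0.16 (camera adjusted p = 0.0522). Leaving out a line ended the calls for immediate-early genes (0.05 without parental, 0.11 without G6, 0.24 without B5), histones (0.61 without parental, 0.79 without G6), lysosome (0.14 without D11, 0.17 without G6, 0.21 without B5) and ribosomal proteins (−0.14 without parental, 0.06 without B5). The lysosome medians were then not below the 0.13 of all lines, so those losses do not show dependence on a line. For the mean of the 3 times, limma gave 0 genes between KO and WT (smallest adjusted p = 0.712), and 613 had an unadjusted p below 0.05.

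In the WT lines at 10 h the largest rises, at a mean of at least 2 log2 CPM and with no overlap, were in MYPN, encoding the sarcomeric protein myopalladin (6.67, SE 0.43, adjusted p = 0.000161), DNER (5.37, SE 1.14, adjusted p = 0.00654), the metalloprotease gene ADAM19 (5.13, SE 0.60, adjusted p = 0.000629), SPOCD1 (4.86, SE 0.45), the replication factor gene MCM10 (4.76, SE 0.48, adjusted p = 0.000436), NAV2 (4.71), NT5E (4.69, SE 0.56, adjusted p = 0.000676) and FAM222A (4.56). The largest falls within the same limits were in the gasdermin gene GSDMB (−5.25, SE 0.41, adjusted p = 0.000286), PI15 (−4.90, SE 0.71, adjusted p = 0.00132), the adhesion molecule gene VCAM1 (−4.71, SE 1.45, adjusted p = 0.0300), KLHL24 (−4.71, SE 0.61, adjusted p = 0.000876), SLC25A27 (−4.60), CALCOCO1 (−4.56), PLEKHS1 (−4.52) and the purinergic receptor gene P2RX7 (−4.46, SE 0.46). In all, 4879 genes passed, 2623 higher and 2256 lower, and 7570 passed with the line as a block. The count was 0 without parental and 31 without D11. The same 0 h libraries serve both serum contrasts of a genotype.

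G1/S genes rose in WT at 10 h with a median of 2.24, led by UHRF1 (4.15), CDC25A (3.71), MCM4 (3.27, SE 0.23, adjusted p = 0.000244) and FEN1 (2.83). Of 65 genes 62 rose and 0 fell, 63 rose adjusted over the list alone, and camera gave adjusted p = 3.16e-23 and adjusted p = 0.699 with an estimated correlation. Ribosome biogenesis genes rose with a median of 1.76, including UTP20 (3.07, SE 0.35), URB2 (2.50), NOP56 (2.43, SE 0.29) and GRWD1 (2.33). Here 32 of 36 rose and 0 fell, 35 rose adjusted over the list alone, and camera gave adjusted p = 2.00e-11 and adjusted p = 0.699 with an estimated correlation. Hypoxia and glycolysis genes had a median of 0.86, with the lactate dehydrogenase gene LDHA at 2.17 (SE 0.26, adjusted p = 0.000676), SLC2A1 at 1.40, BNIP3 at 1.31 and PFKFB4 at 1.26. For them 15 of 27 rose and 2 fell, 15 rose and 3 fell adjusted over the list alone, and camera gave adjusted p = 0.00309 and adjusted p = 0.699 with an estimated correlation. CDK inhibitor and quiescence genes fell with a median of −1.51, including CDKN1C, encoding p57 (−4.64, SE 0.63, adjusted p = 0.00105), TXNIP (−3.33), FOXO4 (−2.94) and BCL6 (−1.96). Of 28 genes 14 fell and 0 rose, 15 fell adjusted over the list alone, and camera gave adjusted p = 9.04e-05 and adjusted p = 0.699 with an estimated correlation. Cholesterol genes fell with a median of −1.66, with MSMO1 (−3.71), HMGCS1 (−3.50, SE 0.37, adjusted p = 0.000487), HSD17B7 (−2.27) and the regulator gene SREBF2 (−2.16). Of 25 genes 17 fell and 0 rose, 17 fell adjusted over the list alone, and camera gave adjusted p = 3.13e-07 and adjusted p = 0.699 with an estimated correlation. Amino acid and ER stress genes fell with a median of −1.19, with CHAC1 (−4.01), TRIB3 (−3.05, SE 0.38, adjusted p = 0.000746), HERPUD1 (−2.81) and DDIT3 (−2.79). Here 17 of 28 fell and 1 rose, 20 fell and 1 rose adjusted over the list alone, and camera gave adjusted p = 5.25e-06 and adjusted p = 0.699 with an estimated correlation.

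In the WT lines at 18 h the genes with the largest rises within these limits included MCM10, GINS2 and CLSPN, which act in DNA replication. MYPN was 6.93 (SE 0.43, adjusted p = 0.000134), FAM111B 5.73 (SE 0.52, adjusted p = 0.000206), MCM10 5.65 (SE 0.48), the cyclin E2 gene CCNE2 5.23 (SE 0.41, adjusted p = 0.000164), ESCO2 5.19 (SE 0.51), GINS2 5.18, CLSPN 5.06 and HELLS 4.84. Genes with the largest falls within them were GSDMB (−5.45, SE 0.41, adjusted p = 0.000164), DDIT4, an mTORC1 inhibitor gene (−5.16, SE 0.84, adjusted p = 0.00183), GDF15 (−4.97, SE 0.63, adjusted p = 0.000649), CHAC1 (−4.90, SE 0.64), VCAM1 (−4.39), the CDK inhibitor gene CDKN2B (−4.13, SE 0.65, adjusted p = 0.00152), P2RX7 (−4.08) and CALCOCO1 (−4.08). In all, 4900 genes passed, 2682 higher and 2218 lower, and 7498 passed with the line as a block. The count was 126 without parental and 315 without D11.

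All 65 G1/S genes rose in WT at 18 h, with a median of 3.55, MCM4 at 3.87 (SE 0.23), FEN1 at 3.49 and RRM1 at 3.01. The same 65 rose adjusted over the list alone, and camera gave adjusted p = 6.97e-32 and adjusted p = 0.699 with an estimated correlation. G2/M genes rose with a median of 2.05, with SKA3 (4.13, SE 0.41), BIRC5 (2.54), RACGAP1 (2.02) and AURKA (1.88, SE 0.20, adjusted p = 0.000338). Of 82 genes 72 rose and 1 fell, both over all genes and adjusted over the list alone, and camera gave adjusted p = 1.49e-18 and adjusted p = 0.699 with an estimated correlation. MuvB, pocket protein and E2F genes had a median of 0.86, with MYBL1 at 3.77, RBL1 at 3.75 and LIN9 at 3.11. For them 12 of 18 rose and 1 fell, 12 rose and 2 fell adjusted over the list alone, and camera gave adjusted p = 0.00392 and adjusted p = 0.699 with an estimated correlation. APC/C genes had a median of 0.41, with FBXO5 at 2.56, MAD2L1 at 2.38, ANAPC7 at 1.78 and UBE2C at 1.71. MAD2L1 and UBE2C are also in the G2/M list. Of the APC/C genes 10 of 22 rose and 0 fell, 10 rose and 1 fell adjusted over the list alone, and camera gave adjusted p = 0.0284 and adjusted p = 0.699 with an estimated correlation. That call was lost without G6 and without B5, with the median unchanged (0.41 each). These clones are not in the contrast, so the loss cannot show that the WT rise depends on them. Ribosome biogenesis genes had a median of 1.35, with 30 of 36 up and 0 down, 32 up adjusted over the list alone, camera adjusted p = 3.24e-08 and adjusted p = 0.763 with an estimated correlation.

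Among lists that fell in WT at 18 h, CDK inhibitor and quiescence genes had a median of −1.34 with CDKN1C at −4.36. Of 28 genes 16 fell and 1 rose, 19 fell and 1 rose adjusted over the list alone, with camera adjusted p = 1.66e-05 and adjusted p = 0.699 with an estimated correlation. Serum immediate-early and delayed-early genes had −1.09, with NR4A1 at −3.88, DUSP5 at −2.50, CTGF at −1.95 and DUSP4 at −1.60. Of 35 genes 11 fell and 4 rose, 12 fell and 4 rose adjusted over the list alone, with camera adjusted p = 0.0284 and adjusted p = 0.699 with an estimated correlation. Cholesterol genes had −1.27, with HMGCS1 at −3.28 and INSIG1 at −2.53. Of 25 genes 16 fell and 0 rose, 17 fell adjusted over the list alone, with camera adjusted p = 1.84e-05 and adjusted p = 0.699 with an estimated correlation. Amino acid and ER stress genes had −1.35, with TRIB3 at −3.64 and HERPUD1 at −3.15. Of 28 genes 20 fell and 1 rose, 23 fell and 1 rose adjusted over the list alone, with camera adjusted p = 2.73e-07 and adjusted p = 0.699 with an estimated correlation. Lysosome and autophagy genes had −0.44, with WIPI1 at −2.56 and MAP1LC3B at −1.47. Of 33 genes 14 fell and 2 rose, the same adjusted over the list alone, with camera adjusted p = 0.0125 and adjusted p = 0.699 with an estimated correlation.

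In the KO clones at 10 h the largest rises, at a mean of at least 2 log2 CPM and with no overlap, were in DNER (5.06, SE 1.14, adjusted p = 0.0157), MYPN (4.71, SE 0.43, adjusted p = 0.00299), the endothelin 1 gene EDN1 (4.56, SE 0.49, adjusted p = 0.00299), ADAM19 (4.50) and SPOCD1 (4.33). Within these limits the largest falls were in the immediate-early gene EGR1 (−4.58, SE 1.10, adjusted p = 0.0193), DDIT4 (−4.44, SE 0.84, adjusted p = 0.00911), PI15 (−4.00), PLEKHS1 (−3.92) and CALCOCO1 (−3.81). G1/S genes rose with a median of 1.26, with CDC25A at 2.86, UHRF1 at 2.62 and MCM4 at 1.90 (SE 0.23, adjusted p = 0.00366). Of 65 genes 44 rose and 0 fell, 50 rose adjusted over the list alone, and camera gave adjusted p = 2.10e-16 and adjusted p = 0.699 with an estimated correlation. Ribosome biogenesis genes had a median of 1.80 with NOP56 at 2.46, 34 of 36 up and 0 down, 36 up adjusted over the list alone, camera adjusted p = 7.46e-17 and adjusted p = 0.699 with an estimated correlation. NF-kB genes had 0.80, with IGFBP3 at 2.32, BIRC3 at 1.88, NFKB1 at 1.03 and RELB at 1.00. Of 20 genes 5 rose and 0 fell, 5 rose adjusted over the list alone, camera gave adjusted p = 0.00896 and adjusted p = 0.699 with an estimated correlation, and the call was lost without B5 (0.24). In all, 3005 genes passed, 1636 higher and 1369 lower, and 6254 passed with the line as a block. No gene passed without parental or without D11, 1880 passed without G6, 4646 without B5, 1364 without the B5 0 h library and 0 when only the groups compared were fitted.

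Within the KO clones, G2/M genes were lower at 10 h than at 0 h with a median of −0.37, with CDC25C at −2.30, the condensin gene NCAPD2 at −1.44, DLGAP5 at −1.43 and PTTG1 at −1.14 (adjusted p = 0.0121). Of 82 genes 7 fell over all genes and 0 adjusted over the list alone, with camera adjusted p = 0.0284 and adjusted p = 0.945 with an estimated correlation. That call was lost with the line as a block and without G6 (−0.11). CDK inhibitor and quiescence genes had −1.33, with CCNG2 at −3.80 and CDKN1C at −3.64, 12 of 28 down, 18 adjusted over the list alone, camera adjusted p = 6.66e-06 and adjusted p = 0.699 with an estimated correlation. Cholesterol genes had −1.59, with MSMO1 at −3.77 and HMGCS1 at −3.67, 20 of 25 down, 21 adjusted over the list alone, camera adjusted p = 1.11e-11 and adjusted p = 0.699 with an estimated correlation. Fatty acid synthesis genes had −0.86, with the desaturase gene SCD at −2.17 and ACSS2 at −2.03, 7 of 15 down, 8 adjusted over the list alone, camera adjusted p = 0.00163 and adjusted p = 0.699 with an estimated correlation. Amino acid and ER stress genes had −0.70, with CHAC1 at −3.35, HERPUD1 at −2.37 and DDIT3 at −1.96. Of 28 genes 8 fell and 2 rose, 9 fell and 2 rose adjusted over the list alone, camera gave adjusted p = 0.00324 and adjusted p = 0.829 with an estimated correlation, and the call was lost without G6 (−0.07). Lysosome and autophagy genes had −0.41, with ULK1 at −1.86 and WIPI1 at −1.49, 9 of 33 down, 10 adjusted over the list alone, camera adjusted p = 0.00234 and adjusted p = 0.699 with an estimated correlation.

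At 18 h in the KO clones EDN1 was 4.47 (SE 0.49, adjusted p = 0.0027), MYPN 4.40 (SE 0.43), DNER 4.11 (SE 1.14, adjusted p = 0.0323), the BMP target gene ID1 3.49 (SE 0.81, adjusted p = 0.0174) and DOK3 3.44 (SE 0.40, adjusted p = 0.00287). DDIT4 was −4.71 (SE 0.84, adjusted p = 0.00748), PNRC1 −3.76 (SE 0.61), KLHL24 −3.72, CHAC1 −3.62 and SLC2A12 −3.54. All 65 G1/S genes rose, with a median of 2.24, CDC25A at 2.99, MCM4 at 2.33, FEN1 at 2.01 and RPA2 at 1.56. The same 65 rose adjusted over the list alone, and camera gave adjusted p = 6.97e-32 and adjusted p = 0.699 with an estimated correlation. G2/M genes had a median of 1.15, with SKA3 at 2.37, BIRC5 at 1.54, RACGAP1 at 1.29 and AURKA at 1.15. Of 82 genes 39 rose and 0 fell, 55 rose adjusted over the list alone, and camera gave adjusted p = 6.40e-13 and adjusted p = 0.716 with an estimated correlation. MuvB, pocket protein and E2F genes had 0.52, with MYBL1 at 2.31, RBL1 at 1.92 and LIN9 at 1.70. Of 18 genes 6 rose and 1 fell, the same adjusted over the list alone, camera gave adjusted p = 0.0055 and adjusted p = 0.699 with an estimated correlation, and the call was lost without G6 (0.45). APC/C genes had 0.44 with FBXO5 at 1.90, 9 of 22 up, 10 up and 1 down adjusted over the list alone, camera adjusted p = 0.0192 and adjusted p = 0.699 with an estimated correlation. The APC/C call was lost without B5, although the median was then 0.46. In all, 2796 genes passed, 1581 higher and 1215 lower, and 5954 passed with the line as a block. The count was 202 without parental, 200 without D11, 1181 without the B5 0 h library and 0 when only the groups compared were fitted.

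Ribosome biogenesis genes in KO at 18 h had a median of 1.44, with NOP56 at 2.12 and NPM1 at 1.49, 30 of 36 up, 36 adjusted over the list alone, camera adjusted p = 1.89e-13 and adjusted p = 0.699 with an estimated correlation. Ribosomal protein genes had 0.36, with RPSA at 0.74, RPL6 at 0.70 and RPL14 at 0.66. Of 50 genes 3 rose over all genes and 0 adjusted over the list alone, camera gave adjusted p = 0.00324 and adjusted p = 0.916 with an estimated correlation, and the call was lost without B5 (0.23). CDK inhibitor and quiescence genes had −1.32, with TXNIP at −2.45 and BTG1 at −1.58, 13 of 28 down, 18 adjusted over the list alone, camera adjusted p = 1.21e-06 and adjusted p = 0.699 with an estimated correlation. Cholesterol genes had −1.22, with HMGCS1 at −3.05 and INSIG1 at −2.59, 14 of 25 down, 18 adjusted over the list alone, camera adjusted p = 1.62e-08 and adjusted p = 0.699 with an estimated correlation. Fatty acid synthesis genes had −0.99, with SCD at −2.49 and FADS2 at −1.99, 8 of 15 down, 9 down and 1 up adjusted over the list alone, camera adjusted p = 0.00324 and adjusted p = 0.699 with an estimated correlation. Amino acid and ER stress genes had −0.59, with HERPUD1 at −2.40 and TRIB3 at −2.12. Of 28 genes 11 fell and 1 rose, the same adjusted over the list alone, camera gave adjusted p = 0.000218 and adjusted p = 0.763 with an estimated correlation, and the call was lost without G6 (−0.25). Lysosome and autophagy genes had −0.45, with 10 of 33 down and 1 up, 11 down and 1 up adjusted over the list alone, camera adjusted p = 0.0012 and adjusted p = 0.699 with an estimated correlation.

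G1/S genes gained less from serum in KO than in WT, with a median difference of −1.09 at 10 h and −1.36 at 18 h. MCM4 was −1.37 at 10 h and −1.53 at 18 h, FEN1 −1.29 and −1.48, and RBL1 −1.32 and −1.83, while BRCA2 was −2.00 at 18 h (adjusted p = 0.281), and none passed in the unblocked fit. MTRNR2L9 was 2.30 at 10 h (adjusted p = 0.495) and 2.66 at 18 h (adjusted p = 0.181). Between KO and WT serum responses limma gave 0 genes at 10 h (756 with an unadjusted p below 0.05, voom 0) and 0 at 18 h (1042 with an unadjusted p below 0.05, voom 0). With the line as a block, which compares each line with itself, 22 genes passed at 10 h (16 higher, 6 lower) and 247 at 18 h (111 higher, 136 lower). At 10 h these included PCNA (−1.36, adjusted p = 0.0418) and MTRNR2L9 (adjusted p = 0.0410). At 18 h they included 26 of the 65 G1/S genes, all lower, among them RRM1 (−1.35, adjusted p = 0.0244), MCM4 (adjusted p = 0.0325), BRCA2 (adjusted p = 0.0325) and FEN1 (adjusted p = 0.0457). RBL1 (adjusted p = 0.0241), MYBL1 (−1.46, adjusted p = 0.0434), MTRNR2L9 (adjusted p = 0.0224) and the spermidine acetyltransferase gene SAT1 (2.07, adjusted p = 0.0193) passed with the block too. The smaller gain in KO started from the higher 0 h level, and at 18 h the centred G1/S medians of parental, D11, G6 and B5 were 1.27, 1.46, 1.16 and 1.17. The G1/S list passed camera at 10 h (adjusted p = 1.01e-25, and adjusted p = 0.699 with an estimated correlation) with 0 genes adjusted over the list alone. It also passed at 18 h (adjusted p = 2.65e-28, and adjusted p = 0.699 with an estimated correlation) with 16 lower adjusted over the list alone.

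By group means G2/M genes also gained less or fell more in KO, with a median difference of −0.40 at 10 h (camera adjusted p = 9.46e-06, and adjusted p = 0.842 with an estimated correlation) and −0.88 at 18 h (camera adjusted p = 1.95e-17, and adjusted p = 0.699 with an estimated correlation). From 0 to 10 h the centred G2/M medians went from −1.22 to −1.42 in parental and −0.73 to −0.37 in D11. In G6 they went from 0.14 to −0.53 and in B5 from −0.19 to −0.26, so B5 did not fall more than parental. With the line as a block 4 G2/M genes were lower at 18 h, among them MKI67 (−2.09, adjusted p = 0.0468), KIF20B (−1.94, adjusted p = 0.0272) and SGOL2 (−1.55, adjusted p = 0.0416). Hypoxia genes had −0.58 at 10 h (camera adjusted p = 7.23e-08, and adjusted p = 0.699 with an estimated correlation) and −0.50 at 18 h (camera adjusted p = 0.00094, and adjusted p = 0.699 with an estimated correlation), with LDHA at −1.57 and −1.64 and BNIP3 at −1.35 and −1.10, and both passed at 18 h with the block (adjusted p = 0.0372 and 0.0483). In each of these 2 hypoxia tests 2 genes were lower adjusted over the list alone. Amino acid and ER stress genes had 0.61 at 10 h (camera adjusted p = 6.97e-06, and adjusted p = 0.699 with an estimated correlation) and 0.64 at 18 h (camera adjusted p = 2.87e-06, and adjusted p = 0.699 with an estimated correlation), with TRIB3 at 1.59 and 1.52. At 18 h the MuvB list had −0.26 (camera adjusted p = 0.00603, and adjusted p = 0.699 with an estimated correlation, 2 lower adjusted over the list alone). Immediate-early genes had 0.41 (camera adjusted p = 0.0122, and adjusted p = 0.699 with an estimated correlation), and NF-kB genes 0.27 (camera adjusted p = 0.0304, and adjusted p = 0.699 with an estimated correlation) with TNFAIP3 at 1.51 (adjusted p = 0.0432 with the block). Without the block 0 members of these lists passed over all genes by limma. Without B5 the amino acid and ER stress median was −0.08 at 10 h and 0.03 at 18 h, MuvB was −0.31 and NF-kB 0.13, and these calls were lost. For MuvB the median was no weaker than the −0.26 of all lines, so its loss does not show dependence on B5. Without G6 the calls for G2/M at 10 h (−0.15), immediate-early genes (0.24) and hypoxia at 18 h (−0.38) were lost, as was NF-kB without D11 (0.04).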

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

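The tests weighed below were chosen only after the results were seen, apart from the other splits of the lines, while the differences in serum response were planned. In 11 tests of gene lists the serum response differed between KO and WT by the camera test of the interaction. At 10 h the median differences were −1.09 for G1/S genes, −0.40 for G2/M genes, −0.58 for hypoxia and glycolysis and 0.61 for the amino acid and ER stress response. At 18 h they were −1.36 for G1/S genes, −0.88 for G2/M genes, −0.26 for MuvB, pocket protein and E2F components, 0.41 for serum immediate-early and delayed-early genes, −0.50 for hypoxia and glycolysis, 0.27 for inflammatory cytokines and NF-kB targets and 0.64 for the amino acid and ER stress response. None of these passed with an estimated correlation, where the smallest adjusted p was 0.699. The amino acid and ER stress differences followed the B5 0 h library. Centred medians at 0 h were 0.94, 1.12, 0.95 and −0.23 in parental, D11, G6 and B5, and from −0.20 to −0.51 in all lines later. The G1/S, G2/M and MuvB differences at 18 h mirrored those at 0 h. Their KO minus WT medians were 1.21, 0.98 and 0.29 at 0 h, and −0.16, 0.02 and −0.07 at 18 h.

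G1/S genes were higher in both KO clones than in both WT lines at 0 h, which bears on the G1/S and G2/M differences in serum response. The spread between control lines is a candidate explanation, as the smaller KO minus D11 median was 0.894 times the D11 minus parental median (0.70 against 0.78). For serum-released cells mixed into the KO libraries, measured ribosome biogenesis medians were −0.43 to 0.0601 where mixtures of 7.56% to 51.5% gave at least 0.182, and measured G2/M medians of 0.55 to 1.39 lay above the mixture's value in all 8 fits, but the clones differed by more than the ribosome biogenesis gap, so the mixture stays open. With 4 lines there are 3 splits into 2 and 2, too few for a share under 0.05, and only the real split, 1 of the 3, reached 97 genes at 0 h, with 3 genes in the highest other. A loss of repression by SIN3B in quiescent cells stays open, as genotype was tested against a spread from n = 2 lines per group and repression itself was not tested.

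The 5 MTRNR2L copies were lower in KO at 0 h, where MTRNR2L10, MTRNR2L8 and MTRNR2L2 no longer passed with the line as a block. Their serum response difference did not pass without the block (MTRNR2L9 adjusted p = 0.495 at 10 h and 0.181 at 18 h), and with it MTRNR2L9, MTRNR2L1 and MTRNR2L2 passed at 10 h and all 5 at 18 h. The copies moved as 1 signal, as the highest SD of a copy-to-copy ratio over the 12 libraries was 0.172 of the SD of their levels, which is consistent with reads shared between near-identical copies. Ribosomal RNA removal that differed between libraries could not be decided, as RNA28S5 was 0.75 higher in KO and RNA45S5 was −1.68, and no mitochondrially encoded gene was in the table. Which copy, or the mitochondrial rRNA itself, supplied the reads stays open.

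More genes passed between KO and WT at 0 h (97) than at 10 h (0 by limma, with 634 at an unadjusted p below 0.05 and 0 by voom) or 18 h (2). By limma, 2299 genes at 0 h and 595 at 18 h had an unadjusted p below 0.05, where 623 are expected by chance. A narrower spread between lines at 0 h is unlikely as the source, since the median within-group variance at 0 h was 0.962 times that at 18 h, and although it was 0.589 times that at 10 h, the fit uses 1 spread per gene for all 6 groups. Deeper libraries are unlikely too, as the mean depth at 0 h was 0.970 times that at 18 h and 0.989 times that at 10 h. The split of D11 and B5 against parental and G6 gave 3 genes at 10 h and 4 at 18 h, more than the real split at these times. A difference between the lines that is larger in starved cells, from SIN3B or from the choice of lines, stays open.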

How the results depend on the processing

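Voom, leaving out the B5 0 h library and the other scalings of list medians were chosen after seeing the data. For KO against WT at 0 h the 97 genes became 53 with a mean of at least 2 log2 CPM, 278 with quantile normalization, 149 with a pseudocount of 1 CPM, 0 with only the groups compared, 28 with the line as a block and 10 without the B5 0 h library. No filter (125), median-centred values (122), no variance trend (67), a log2 fold change of at least 1 (86) and voom (100, of which 80 were shared) stayed within 1.5 times. At 10 h the 0 genes by limma (634 at an unadjusted p below 0.05, 0 by voom) became 2 with median-centred values, 1 with quantile normalization, 2 with a pseudocount of 1 CPM, 2 with no variance trend, 1 with the line as a block and 1 without the B5 0 h library. At 18 h the 2 genes became 0 with a mean of at least 2 log2 CPM, 1 with median-centred values, 1 with quantile normalization, 1 with no variance trend, 0 with only the groups compared, 5 with the block and 1 with voom. Serum in WT at 10 h gave 7570 genes with the block and 3218 with a log2 fold change of at least 1, beside 4879, and at 18 h 7498 and 3266, beside 4900. Serum in KO at 10 h gave 6254 with the block, 1891 with a log2 fold change of at least 1, 0 with only the groups compared and 1364 without the B5 0 h library, beside 3005. At 18 h it gave 5954, 1786, 0 and 1181, beside 2796. The difference in serum response gave 22 genes at 10 h and 247 at 18 h with the block, where limma gave 0 without it (756 and 1042 at an unadjusted p below 0.05, 0 by voom). Leaving out a line moved the counts from 0 to 1353 for KO against WT at 0 h, 0 to 706 at 10 h, 0 to 307 at 18 h and 0 to 354 for the mean of 3 times, from 0 to 7050 and 126 to 6997 for WT serum at 10 and 18 h, and from 0 to 4646 and 200 to 3645 for KO serum. The counts were lowest without a WT line for every KO against WT contrast, and highest without G6 there. With a line left out, the spread came from the lines of the other genotype alone. The median absolute log2 difference was 0.32 to 0.46 between B5 and G6 and 0.17 to 0.23 between D11 and parental. These counts therefore do not show which line carries a difference. Fewer genes tested, fewer libraries in the spread and the size limit are part of how the filter, the groups compared, the left-out line and the fold limit were built, and for the other settings the cause was not tested.

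Of 22 genes named at 0 h for KO against WT, 22 stayed past the threshold without a filter, with median-centred or quantile values, with a pseudocount and without G6, 17 with a mean of at least 2 log2 CPM, 13 without the variance trend, 15 with voom, 15 without B5, 9 with the block, 2 without the B5 0 h library, and 0 with only the groups compared, without parental or without D11. RPS2 in KO at 18 h (0.81) newly passed with the block (adjusted p = 0.00355). For the lists and the genes that the naming rule gives, the block changed no other call beyond those given here and beside each result. Over all named genes and settings other than a left-out line 3044 of 3280 values kept their direction and side of the threshold, 206 no longer passed, 29 newly passed and 1 reversed. That was the serum response difference of SIN3B at 18 h, which was 0.0166 with quantile normalization, and it did not pass in either. With a line left out 912 of 1316 kept both, 370 no longer passed, 27 newly passed and 7 reversed. Ranges with a line left out that crossed 0 were −0.10 to 1.23 for HIST1H1C, −0.34 to 1.95 for HIST2H2BE and −0.12 to 1.32 for HIST1H2AC at 10 h, −0.15 to 1.59 for HIST1H2AC at 18 h, and −0.34 to 0.14 at 10 h and −0.22 to 0.0829 at 18 h (0.06 without D11) for the serum response difference of SIN3B. The SIN3B difference between KO and WT did not pass under any setting.

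Of 65 list calls 0 passed with an estimated correlation (smallest adjusted p = 0.699), including G1/S genes (1.21) and G2/M genes (0.98) at 0 h. The preset value assumes nearly independent genes. The estimated one also failed for G1/S genes at 18 h against 0 h in WT, where all 65 genes rose. Failing it therefore does not show that a list is unchanged. Of the 63 list calls other than those for G1/S and G2/M genes at 0 h, 61 passed with the block. The block and the left-out lines were judged by cameraPR, so a lost call can reflect the change of test. With a line left out 212 of 252 kept direction and threshold, 36 no longer passed and 4 reversed: cytosolic ribosomal proteins in KO against WT (−0.53 to 0.0600 at 0 h, −0.34 to 0.0614 at 18 h), replication-dependent histones at 10 h (−0.11 to 1.49) and the amino acid and ER stress response in the serum difference at 10 h (−0.0776 to 1.11). No call among the 65 changed the sign of its median under the 4 other scalings. Depth limits genes near 3 reads, which equal 0.107 to 0.147 CPM, and the filter at 0 log2 CPM lies above them. The cause of these changes was not tested.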

Other observations

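The correlations with simulated controls were planned, and the checks of later times were chosen only after the 0 h result was seen. The integrin gene ITGA7 had a mean of 0.14 log2 CPM over the 12 libraries, just above the filter at 0. It was higher in KO at 0 h (4.25, adjusted p = 0.0226), with 4.64 at 10 h (adjusted p = 0.0525) and 3.98 at 18 h (adjusted p = 0.115). With a line block it passed at 10 and 18 h. At 0, 10 and 18 h EFEMP1 was −2.47, −3.16 and −3.44 and the fibrillin gene FBN2 −1.80, −2.17 and −2.24, neither past the threshold without the block, and with it both passed at 18 h alone. The sodium channel gene SCN3A was 3.47 at 0 h (adjusted p = 0.0515), 2.56 at 10 h and 2.47 at 18 h. The proapoptotic gene BBC3 fell after serum in WT at 10 h by 5.28 (adjusted p = 0.000412) and in KO by 3.29 (adjusted p = 0.00567). The ornithine decarboxylase gene ODC1 rose by 2.78 in WT and 2.38 in KO, and HBEGF by 3.90 and 2.97. These genes were chosen after their values were seen.

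Genes that differed at 0 h had smaller differences later, although genes picked for passing at 0 h have their values there biased away from 0. Of 42 genes higher in KO at 0 h, 41 were above 0 at 10 h and 34 at 18 h, with a median of 1.49 at 0 h, 0.40 at 10 h and 0.25 at 18 h. Of 55 lower genes 43 were below 0 at 10 h and 31 at 18 h, with medians of −1.46, −0.31 and −0.07. At an unadjusted p below 0.05 and with the same sign were 16 and 14 of the higher and 19 and 16 of the lower genes. Of the 42 higher genes 38 also rose in WT between 0 and 18 h, where independent lists give 9.04 and simulated unchanged groups with the same shared WT libraries a mean of 34.0 (28 to 40). Of the 55 lower genes 44 also fell in WT, against 9.79 and 41 (32 to 49). Both counts lie inside the simulated range, but the simulated groups had no serum response, while 4900 genes passed in WT at 18 h. They therefore cannot tell what overlap the shared libraries alone would give in these data. The same limit holds for the correlation of the 2 effects over all genes, which was 0.483, against 0.499 in simulated groups. The covariance was 0.355, above the simulated mean of 0.0954 (0.0841 to 0.112). The WT lines cannot be split without leaving 1 line on each side.

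The 2 KO clones shared more of their change at 0 h than later. The correlation of G6 and B5 against the WT mean was 0.429 at 0 h, −0.0643 at 10 h and 0.0579 at 18 h, against 0.334, 0.332 and 0.335 in simulated groups with shared controls. The share of genes with the same sign was 69.5%, 45.3% and 51.2%, against 60.9%, 60.8% and 60.8%. With separate controls the correlation was 0.360, −0.108 and −0.0248, and with the controls crossed 0.241, −0.226 and −0.0595. The median absolute log2 difference between lines was 0.21, 0.23 and 0.17 for D11 and parental at 0, 10 and 18 h, and 0.32, 0.46 and 0.37 for B5 and G6. The simulated groups gave WT and KO lines the same spread, so their values are not an exact baseline for the agreement of the clones. The first principal component held 50.9% of the variance and parted 0 h from later libraries, and the second held 17.7% with B5 at −42.4, −46.9 and −55.3 at the 3 times.

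No call was made in any contrast for 6 tested lists. At 0 h the KO minus WT medians were 0.09 for the Sin3/HDAC complex and partners (camera adjusted p = 0.715), 0.12 for p53 targets (0.968), 0.36 for neuronal genes (0.424), −0.01 for astrocyte and glial progenitor genes (0.684), −0.08 for the interferon response (0.724) and −0.38 for 3 markers of other cell types (0.329). The centred interferon medians of parental, D11, G6 and B5 were −0.27, 0.71, −0.22 and 0.44 at 0 h, so they followed the line and not the genotype. They were −0.31, 0.54, −1.29 and 0.57 at 10 h and −0.03, 0.53, −0.93 and 0.35 at 18 h. On GRCh38, SIN3B lies at 19:16829400-16880353, IL7R at 5:35852695-35879603, NT5E at 6:85449584-85495791, VCAN at 5:83471465-83582303 and CDH6 at 5:31193750-31329146.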
